A study of Mus musculus with 20 samples.

How the data were processed

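RNA of 20 testis samples from male NSG mice, an immunodeficient strain that accepts human cells, was measured by poly(A)-selected RNA sequencing. Per the labels' protocols, engrafted mice received 400000 patient-derived human B-cell acute lymphoblastic leukaemia (B-ALL) cells into the tail vein at an age of 6 weeks. Vincristine sulfate, a drug that binds tubulin, was injected into the peritoneum at 0.5 mg/kg once weekly for 3 weeks from day 69, and control mice received saline. RNA was extracted with TRIzol, selected with oligo-dT beads and made into directional libraries, also per the labels' protocols. The 5 groups of 4 samples were untreated controls (NC), engrafted and not given the drug (ALL), vincristine (VCR), and engrafted, vincristine-treated mice with low (Low-VCR) or high (High-VCR) leukaemia infiltration of the peripheral blood. The labels of the VCR group name no injected cells. Samples were placed in groups by their titles, and the labels record 1 deposited batch.

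The deposited table held whole-number counts per gene symbol, not normalised. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.10b, featureCounts of Subread 2.0.3 and DESeq2 1.36.0 were named with the build GRCm39 (mm39). The roles of these tools, the annotation, the strand setting, and whether human reads were removed were not given in the sources used here. The table had 22066 symbols, of which 20257 matched a RefSeq gene table and 20106 a GENCODE annotation of the older build GRCm38. Those references served only to check names, and no coordinates are given. Symbols of overlapping genes, or of families of near-identical copies such as Btbd35f15, the tubulins and the ribosomal proteins, carry the uncertainty of how the authors' counting divided shared reads.

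Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of the symbols, 1207 had no count, and 16534 passed edgeR's filterByExpr by group (minimum count 10) and were tested. One quasi-likelihood fit (glmQLFit, robust, TMM scaling) of 5 group means over 20 libraries, with 15 residual degrees of freedom, gave each comparison through glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The comparisons were ALL against NC, VCR against NC, Low-VCR against ALL, High-VCR against ALL, High-VCR against Low-VCR, Low-VCR against VCR and High-VCR against VCR. A pair of interactions asked whether the response of Low-VCR or High-VCR relative to ALL differed from that of VCR relative to NC. Standard errors of log2 fold changes were computed from the fold change and the F statistic. CPM values were scaled by TMM. Tssk4 and Ccdc159, named in the series title, were also tested by exact two-sided permutation of log2(CPM + 1), adjusted over both genes and all pairwise comparisons; with 4 samples against 4 the smallest possible p is 0.0286.

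The groups, comparisons, tests, 34 gene lists with 663 genes, most alternatives and the rule for named genes were fixed before the data were examined. That rule took Tssk4 and Ccdc159 in every comparison. In each pairwise comparison it also took the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 1 CPM in the higher group and no overlap of the values of the groups. From each list with a called member it took the 2 members with the smallest adjusted p, and from each interaction the 3 called genes with the smallest adjusted p. Where fewer than 3 genes passed, the 3 with the smallest p were taken and given as not passing. Symbols of unnamed gene models, Xist and Y-linked genes were counted but not named. In the High-VCR against Low-VCR, Low-VCR against VCR and High-VCR against VCR comparisons, members were left out for length. Lists were tested with limma's camera at an inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. Lists with fewer than 4 measured members were not tested. List scores are means over the members of a list of edgeR's log2 CPM, with a prior count of 1, in a library.

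Genes listed at 0 in all 4 libraries of a group have no fitted fold change in the text. Their fold was bounded against 3 counts summed over that group. The same bound is used where leaving out 1 library leaves a group at 0. With 1 to 3 counts the ratio of summed counts is given with an exact 95% interval, and in an interaction the ratio of both ratios with the exact Poisson interval of the low count alone. Such intervals and floors cover counting error only. The deposited totals lay between 9.43 and 16.4 M (mega) counts per library, so 3 counts corresponded to 0.167 to 0.365 CPM in a single library. The labels give separate samples per group but do not state that each came from a separate mouse, so p-values measure the spread between these samples.

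The alternatives were DESeq2 size factors in edgeR, library size alone, upper-quartile scaling, no gene filter, a filter of 1 CPM in 4 samples, DESeq2 1.42.0, limma voom with sample quality weights, a log2 fold threshold of 1, a fit of only the groups compared, the replicate number as a block, the range of library numbers as a covariate in the engrafted groups, and leaving out each library in turn. Scaling on the Sertoli cell list and a fit of only the 12 vincristine-treated libraries were added after the data had been seen. The steps were tested on simulated counts with 200 changed genes among 15612 to 15623. For VCR against NC, 61% and 88% of genes changed by 1 and 2 on the log2 scale were recovered, and 4.118% of calls were false. The data had 12851 calls there and unequal spreads, so these shares may not apply. For ALL against NC with the spread of all groups the shares were 49% and 87%, with 3.268% false calls. With the smaller spread of NC and ALL they were 94% and 100%, with 8.974% false. For High-VCR against VCR they were 58% and 82%, with 5.59% false.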

Results

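Testis RNA was profiled in 5 groups of 4 samples. NC held untreated controls, ALL held mice engrafted with human B-ALL cells and given no drug, and VCR held mice given vincristine. Low-VCR and High-VCR held engrafted mice given vincristine, with low or high leukaemia infiltration of the peripheral blood. Total counts per library were 9.43 to 15 M (mega) in NC, 10.3 to 11.8 M in ALL, 10.6 to 14 M in VCR, 13 to 13.9 M in Low-VCR and 13.1 to 16.4 M in High-VCR. Of 22066 gene symbols, 16534 were tested. In the following, values written as a number ± a number are log2 fold changes ± standard errors from edgeR with n = 4 per group, unless another unit is named. "Rose" and "fell" refer to genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested.

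The libraries of vincristine-treated mice lay apart from those of untreated mice. The first principal component of log2 CPM held 69.7% of the variance, with the untreated libraries between -125.4 and -108.7 and the treated ones between 0.4 and 238.3. VCR 1 lay farthest from the untreated libraries, at 238.3. Counts of mitochondrially encoded genes were 2.23% ± 0.316 of all counts in NC (SD, n = 4), 1.95% ± 0.136 in ALL, 8.28% ± 2.62 in VCR, 6.08% ± 1.53 in Low-VCR and 7.32% ± 1.91 in High-VCR. The biological coefficient of variation was 13.9% in NC, 9.33% in ALL, 46.9% in VCR, 26% in Low-VCR and 32.9% in High-VCR, and 29.8% in the fit shared by all groups. No pair of libraries of a group agreed within counting noise. The library numbers of NC and VCR formed a range of their own, so comparisons of these groups with engrafted groups cannot be told apart from that range. The engrafted groups shared a pair of other ranges, with 2 libraries of each group in each.

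**Figure D1:**
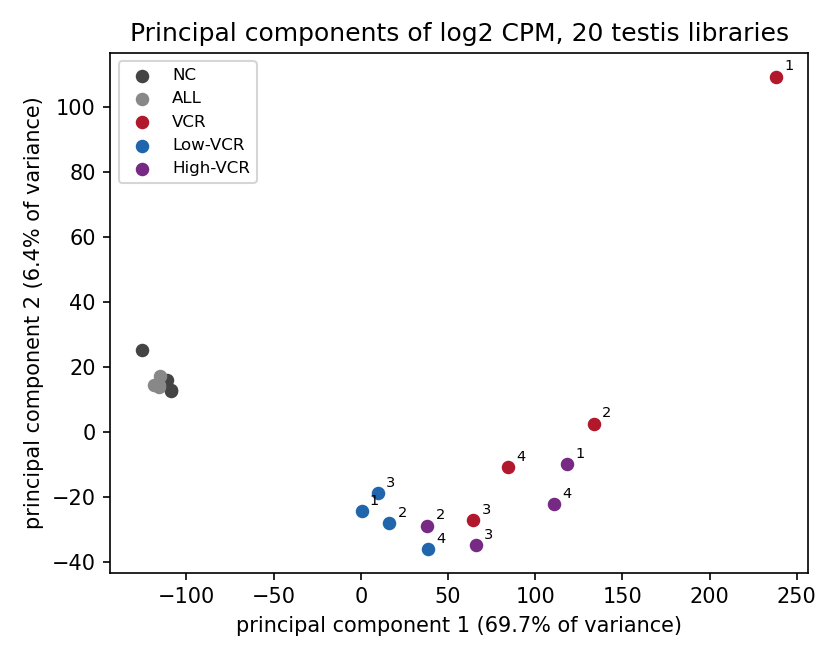
Principal components 1 (69.7% of variance) and 2 (6.4%) of log2 CPM in 20 testis libraries, each a point, coloured by group. The 8 untreated libraries lie together at -108.7 or below on component 1, and VCR 1 lies at 238.3.

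The series title names Tssk4, a testis-specific serine/threonine kinase, and Ccdc159, a coiled-coil gene. Tssk4 was at 108 ± 9.08 CPM in NC (SD, n = 4), 87.1 ± 5.42 in ALL, 4.26 ± 3.38 in VCR, 37.9 ± 25.5 in Low-VCR and 6.16 ± 3.27 in High-VCR. It fell 25.2-fold in VCR relative to NC (-4.65 ± 0.73, adjusted p 2.21e-05) and 14.2-fold in High-VCR relative to ALL (-3.82 ± 0.70, adjusted p 0.000119). In Low-VCR relative to ALL it did not pass (-1.20 ± 0.63, adjusted p 0.111), nor in ALL relative to NC (-0.31 ± 0.62, adjusted p 1). Low-VCR was above VCR (3.14 ± 0.69, adjusted p 0.00552), a call lost with only those groups (adjusted p 0.108) or only the 12 treated libraries (0.0543). High-VCR was below Low-VCR (-2.62 ± 0.67, adjusted p 0.029). That call was lost without High-VCR 1 or 4 (adjusted p 0.0884 and 0.105) or Low-VCR 1 or 3 (0.0854 and 0.0972), and with only those groups (0.0748) or the treated libraries (0.178). High-VCR did not pass relative to VCR (0.52 ± 0.67, adjusted p 0.869).

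Ccdc159 was at 46.7 ± 3.82 CPM in NC (SD, n = 4), 30.8 ± 13.1 in ALL, 4.93 ± 6.61 in VCR, 27 ± 8.62 in Low-VCR and 11.8 ± 8.82 in High-VCR. It fell 9.33-fold in VCR relative to NC (-3.22 ± 0.86, adjusted p 0.00258; -4.61 without VCR 3). Low-VCR was above VCR (2.43 ± 0.84, adjusted p 0.0374; 3.82 without VCR 3). That call was lost without Low-VCR 1, 2 or 4 (adjusted p 0.0669, 0.0796 and 0.0511) or VCR 1, 2 or 4 (0.0562, 0.0817 and 0.0574), and with only those groups (0.195) or the treated libraries (0.133). Ccdc159 did not pass for ALL relative to NC (-0.60 ± 0.78, adjusted p 1). Nor did it for High-VCR relative to Low-VCR (-1.19 ± 0.79, adjusted p 0.339), VCR (1.24 ± 0.82, adjusted p 0.748) or ALL (-1.38 ± 0.80, adjusted p 0.126, but -2.04 and 0.0491 without High-VCR 3). For Low-VCR relative to ALL (-0.19 ± 0.78, adjusted p 0.84) the sign turned without ALL 1 (0.12) and with library size alone (0.06). VCR 1 had 0 counts of either gene (3 counts are 0.229 CPM) and VCR 2 had 1 of Ccdc159 and 73 of Tssk4.

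In exact two-sided permutation tests of these genes, Tssk4 reached the smallest possible p of 0.0286 (adjusted 0.0572 over 14 tests) for VCR and ALL relative to NC, Low-VCR and High-VCR relative to ALL, and Low-VCR relative to VCR. Ccdc159 reached it for VCR relative to NC and Low-VCR relative to VCR.

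**Figure D2:**
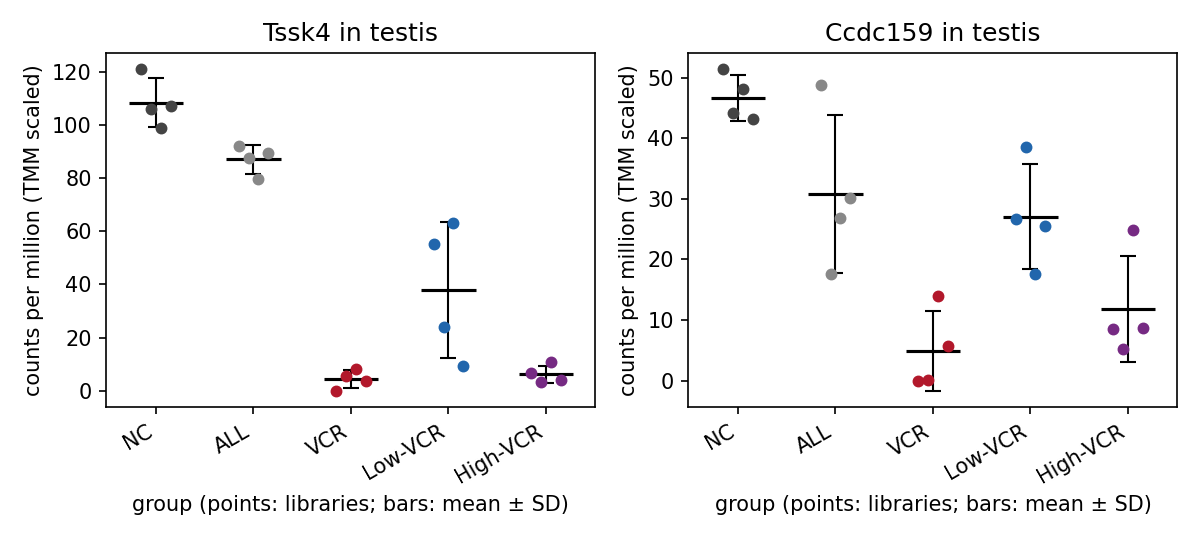
CPM (TMM scaled) of Tssk4 and Ccdc159 by group; points are libraries, bars are means ± SD (n = 4). Tssk4 averages 108 CPM in NC and 4.26 in VCR.

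The comparison of ALL with NC asks what engraftment did without the drug. No gene passed in the edgeR fit of all 5 groups, with 748 genes at an unadjusted p under 0.05. The genes with the smallest p did not pass: Osbpl1a, an oxysterol-binding protein gene, was at 53.8 ± 3.25 CPM in ALL and 26.5 ± 6.19 in NC (SD; 1.02 ± 0.16, adjusted p 0.0676). Snhg4, a small nucleolar RNA host gene, was at 3.90 ± 0.925 and 0.183 ± 0.365 CPM (4.59 ± 0.83, adjusted p 0.2), and the zinc finger gene Zfp820 at 15.1 ± 3.71 and 34.4 ± 8.3 CPM (-1.19 ± 0.22, adjusted p 0.2). No list was called by camera. The smallest adjusted p was 0.0535, for inflammatory and acute-phase genes (median 0.11) and cytosolic ribosomal proteins (0.02), followed by 0.0565 for endothelial cells (0.12) and Sertoli cells (-0.18). Adjusted over the list alone, 1 gene of cholesterol synthesis was lower, 1 peritubular gene higher and 1 lower, and 1 inflammatory and 1 glucocorticoid-induced gene higher. Round spermatids had a median of -0.05 and leptotene and zygotene genes of -0.13. Interferon-stimulated genes had a median of -0.21 (-0.20 with Cxcl10, listed at 0 in ALL, at its bound).

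Other tools gave other counts for ALL relative to NC: DESeq2 called 19 genes, limma voom 104, and edgeR with only these groups 28 (20 higher, 8 lower). One gene was called without ALL 3, ALL 4 or NC 1, and 2 without NC 4. No B lineage gene passed (0 of 13 measured, median 0.16), with a list score of 1.39 ± 0.30 in ALL and 1.12 ± 0.17 in NC (SD, n = 4). In simulated counts with the spread of all groups this comparison recovered 49% of genes changed by 1 on the log2 scale, and human transcripts were not analysed here. The simulation gave all groups the same spread, unlike the data, so that share may not apply.

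The comparison of VCR with NC asks what vincristine did in the testis; the labels of VCR name no injected cells. Genes of late germ cells fell together: all 24 round spermatid genes (median -2.82), all 25 genes of elongating and condensing spermatids (-2.30), all 7 testis-specific serine kinases and their substrate (-2.74) and 25 of 29 sperm flagellum and manchette genes (-2.02, 26 adjusted over the list alone). Catsper1 and Catsper3, subunits of the sperm calcium channel, fell by 3.83 ± 0.46 and 4.66 ± 0.61. Ropn1 and Akap3, of the fibrous sheath of the sperm tail, fell by 2.90 ± 0.52 and 2.7 ± 0.53. Tssk5 fell from 49.3 to 0.725 CPM (-6.08 ± 0.85) beside Tssk4, and the tektin Tekt2 and the flagellar gene Armc2 fell by 3.67 ± 0.57 and 2.19 ± 0.32. Meiotic genes fell as well: 18 of 22 pachytene to diplotene genes (median -1.70, 19 adjusted over the list alone) and 19 of 29 leptotene and zygotene genes (-1.17). The meiotic cohesin Rec8 fell by 4.03 ± 0.52, the synaptonemal complex gene Syce2 by 2.13 ± 0.30, the phosphatase Cdc25c by 2.41 ± 0.31 and the chaperone Calr3 by 2.25 ± 0.40. Each of these genes had an adjusted p of at most 0.000189. VCR 1 had a round spermatid score of 1.45, and the other VCR libraries 4.77 or above.

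Spermatogonial genes went both ways in VCR. Undifferentiated spermatogonia had 6 of 14 genes higher and 2 lower (median 0.77, and -0.99 when libraries were scaled on the Sertoli list, a scaling added after the data had been seen and called Sertoli scaling below). Differentiating spermatogonia had 3 of 14 higher and 6 lower (5 adjusted over the list alone; median -0.47). Tspan8 rose by 3.23 ± 0.37, the transcription factor gene Foxo1 by 1.51 ± 0.18, the receptor gene Kit from 11.4 to 95.8 CPM (3.07 ± 0.25) and the cyclin gene Ccnd2 by 2.84 ± 0.30. Kit is also expressed in Leydig and mast cells. Mitotic spindle and checkpoint genes fell (16 of 23, median -1.10), among them Ccnb1 (-1.87 ± 0.28) and Cenpe (-1.58 ± 0.27). Of 15 tubulin genes, which encode the target of the drug, 6 rose and 8 fell (median -1.13); Tubb3 rose by 2.40 ± 0.23 and Tubb5 by 2.17 ± 0.22. Their adjusted p was at most 5.09e-05.

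Beside Tspan8, Kit and Ccnd2, genes of somatic cells rose in VCR. Sertoli cells had 21 of 22 genes higher (median 1.92), Leydig cells and steroidogenesis 14 of 15 higher and 1 lower (2.65), and endothelial cells 13 of 15 higher (2.07). Shbg rose by 2.82 ± 0.22, the inhibin alpha gene Inha by 2.19 ± 0.19, the steroidogenic factor Nr5a1 by 2.87 ± 0.21 and Hsd3b1, a steroid dehydrogenase of androgen synthesis, from 31.3 to 459 CPM (3.88 ± 0.30). Kdr, a receptor for VEGF, rose by 3.18 ± 0.24 and Ly6c1 by 4.22 ± 0.35. Cholesterol synthesis (16 of 22 higher, 2 lower, median 1.53), junctions of the blood-testis barrier (10 of 16 higher, 3 lower, 1.32) and peritubular and smooth muscle cells (10 of 13 higher, 1 lower, 1.48) had medians below 0 under Sertoli scaling. Ebp and Dhcr7, sterol synthesis enzymes, rose by 2.05 ± 0.19 and 2.66 ± 0.26. The junction molecules F11r and Jam2 rose by 2.36 ± 0.18 and 3.69 ± 0.31, and the contractile genes Myl9 and Acta2 by 1.82 ± 0.18 and 1.76 ± 0.19. The adjusted p of these genes was at most 3.05e-07.

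Immune genes rose in VCR. Of 24 interferon-stimulated genes 23 rose (median 2.89), of 19 macrophage and monocyte genes 17 rose and 1 fell (3.23), and of 17 inflammatory and acute-phase genes 14 rose and 1 fell (3.44). The guanylate-binding protein gene Gbp2 rose by 3.97 ± 0.31 and the immunoproteasome gene Psmb8 by 3.45 ± 0.27. Lyz2, the lysozyme of myeloid cells, rose by 3.56 ± 0.24 and the complement gene C1qa by 3.23 ± 0.23. The acute-phase gene Serpina3n rose 55.6-fold (5.80 ± 0.40) and complement C3 from 21.9 to 414 CPM (4.24 ± 0.35). Neutrophil genes rose in 3 of 4 measured (median 2.07), with Camp at 2.61 ± 0.38 and Csf3r at 1.53 ± 0.26. Extracellular matrix genes rose in 18 of 21 and fell in 2 (2.06), with Timp1, an inhibitor of metalloproteinases, at 4.59 ± 0.33 and Sparc at 2.51 ± 0.20. B lineage and leukocyte genes had 7 of 13 higher and 2 lower (median 1.11, below 0 under Sertoli scaling), with Cd53 at 3.39 ± 0.28 and Mme at 2.64 ± 0.22. Each of these genes had an adjusted p of at most 3.84e-05.

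Stress genes rose in part in VCR. Median changes of 1.67 for p53 targets (17 of 22 higher, 3 lower), 1.20 for core apoptosis genes (16 of 22 higher, 17 adjusted over the list alone, 3 lower), 0.93 for NRF2 and antioxidant genes (12 of 19 higher, 3 lower), 1.48 for hypoxia-induced genes (13 of 18 higher, 3 lower) and 0.29 for heat shock genes (11 of 21 higher, 9 lower) all turned below 0 under Sertoli scaling. Ccng1 and Sesn2, p53 targets, rose by 2.60 ± 0.23 and 1.72 ± 0.16. The inhibitor of apoptosis Birc3 rose by 2.7 ± 0.18 and the caspase gene Casp6 by 1.91 ± 0.15. G6pdx, of the pentose phosphate pathway, and the glutathione peroxidase Gpx1 rose by 2.59 ± 0.19 and 2.85 ± 0.24. Bnip3 and Pdk1, induced by hypoxia, rose by 1.99 ± 0.18 and 1.87 ± 0.17, and the chaperones Hspb1 and Hspd1 by 1.94 ± 0.18 and 2.10 ± 0.22. Immediate early genes had 8 of 15 higher and 6 lower (median 1.94), with Ier2 at 2.04 ± 0.19 and Ier3 at 3.58 ± 0.34. Glucocorticoid-induced genes had 9 of 14 higher and 3 lower (1.82), among them Lcn2, also an acute-phase gene, from 67.9 to 2290 CPM (5.07 ± 0.43) and Ddit4 (1.86 ± 0.17). Their adjusted p was at most 2.23e-07.

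All 13 mitochondrially encoded genes rose in VCR (median 1.52) beside the higher mitochondrial share, and 33 of 44 cytosolic ribosomal protein genes rose and 5 fell (0.58); both medians were below 0 under Sertoli scaling. mt-Nd4l rose by 1.76 ± 0.28, mt-Co3 by 1.52 ± 0.25, Rps3 by 1.59 ± 0.15 and Rps19 by 1.70 ± 0.16. Erythroid genes rose in 5 of 7 and fell in 1 (median 1.85), with the globin Hbb-bs at 3.18 ± 0.47 and Alas2 at 1.26 ± 0.20. Of 6 adipocyte genes 2 rose and 2 fell (median -0.05, and 0.34 with library size alone or 0.11 with upper-quartile scaling), with Adipoq at -3.21 ± 0.62 and Plin4 at 2.01 ± 0.46. Of 3 epididymis genes Cst8 fell (-1.70 ± 0.23) and Cst11 rose (1.42 ± 0.48, adjusted p 0.0128), a call lost without NC 4 or VCR 2 (adjusted p 0.0501 to 0.0632). The adjusted p of the other genes was at most 0.000795.

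The largest rises in VCR were of genes listed at 0 in all 4 NC libraries. Myc, a growth regulator, was at 10.2 ± 5.56 CPM in VCR (SD, n = 4; at least 136-fold higher), Wfdc18 at 8.07 ± 5.26, Itih4 at 6.51 ± 3.79 (at least 87-fold), Lcn3 at 4.89 ± 3.01 (64.9-fold), the B cell surface gene Cd72 at 3.72 ± 1.34 (50.4-fold) and Pcdhga7 at 3.09 ± 1.34 (41.6-fold). Genes listed at 0 in all 4 VCR libraries were Myt1 (7.01 ± 3.19 CPM in NC, at least 136-fold lower), the urate transporter Slc2a9 (4.02 ± 1.26, at least 74-fold), H2-M5 (3.81 ± 0.667, at least 68.2-fold) and Dnajc6 (1.82 ± 1.25, at least 35.9-fold; not called by limma voom). The floor was 3 counts summed over the group. Pacs2 fell from 328 ± 17.7 to 0.951 ± 1.9 CPM, with all 58 VCR counts in VCR 3 (-8.35 ± 1.47; listed at 0 without VCR 3, at least 4280-fold lower). Btbd35f15 had 249 counts in NC and 1 in VCR, in VCR 2, a ratio of 331 (95% interval 58.9 to 13100; listed at 0 without VCR 2, at least 83.8-fold lower). The adjusted p of these genes was at most 0.00792. A count of 0 may not mean absence in this table, since 20 of 9374 genes with a mean of at least 100 counts in the 8 untreated libraries, such as Rps14, were listed at 0 in 1 or more of them.

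Altogether 12851 of 16534 genes passed for VCR relative to NC, 6960 higher and 5891 lower (54.2% higher), and 9407 of them changed at least 2-fold; 12168 passed without VCR 1. Scaling changed the split: 6488 were higher and 6493 lower with DESeq2 size factors, 6489 and 6566 in DESeq2, 8309 were higher and 4480 lower with library size alone (65% higher), and 1429 higher and 12217 lower under Sertoli scaling (10.5%). The median log2 fold change of all genes moved by 0.39 with library size alone, 0.17 with the upper quartile, -0.12 with DESeq2 size factors and -1.78 under Sertoli scaling. Camera called 16 lists up and 7 down in VCR. With an estimated correlation it called 0 up and 0 down: the adjusted p was then 0.487 for cholesterol synthesis and 0.451 for every other called list. Not called at the preset correlation were both spermatogonial lists (0.346 and 0.387), neutrophils (0.146), erythroid cells (0.161), B lineage (0.428), adipocytes (0.897), tubulins (0.692), immediate early genes (0.809), heat shock genes (0.743) and glucocorticoid-induced genes (0.0692). Under Sertoli scaling Bnip3, Casp6, Ddit4, Ebp, Hspb1, Hspd1, Ier2, Pdk1 and Plin4 no longer passed, and the sign of Acta2, Alas2, Csf3r, Cst11, Foxo1, Sesn2, mt-Co3, mt-Nd4l, Myl9, Rps3 and Rps19 turned.

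**Figure D3:**
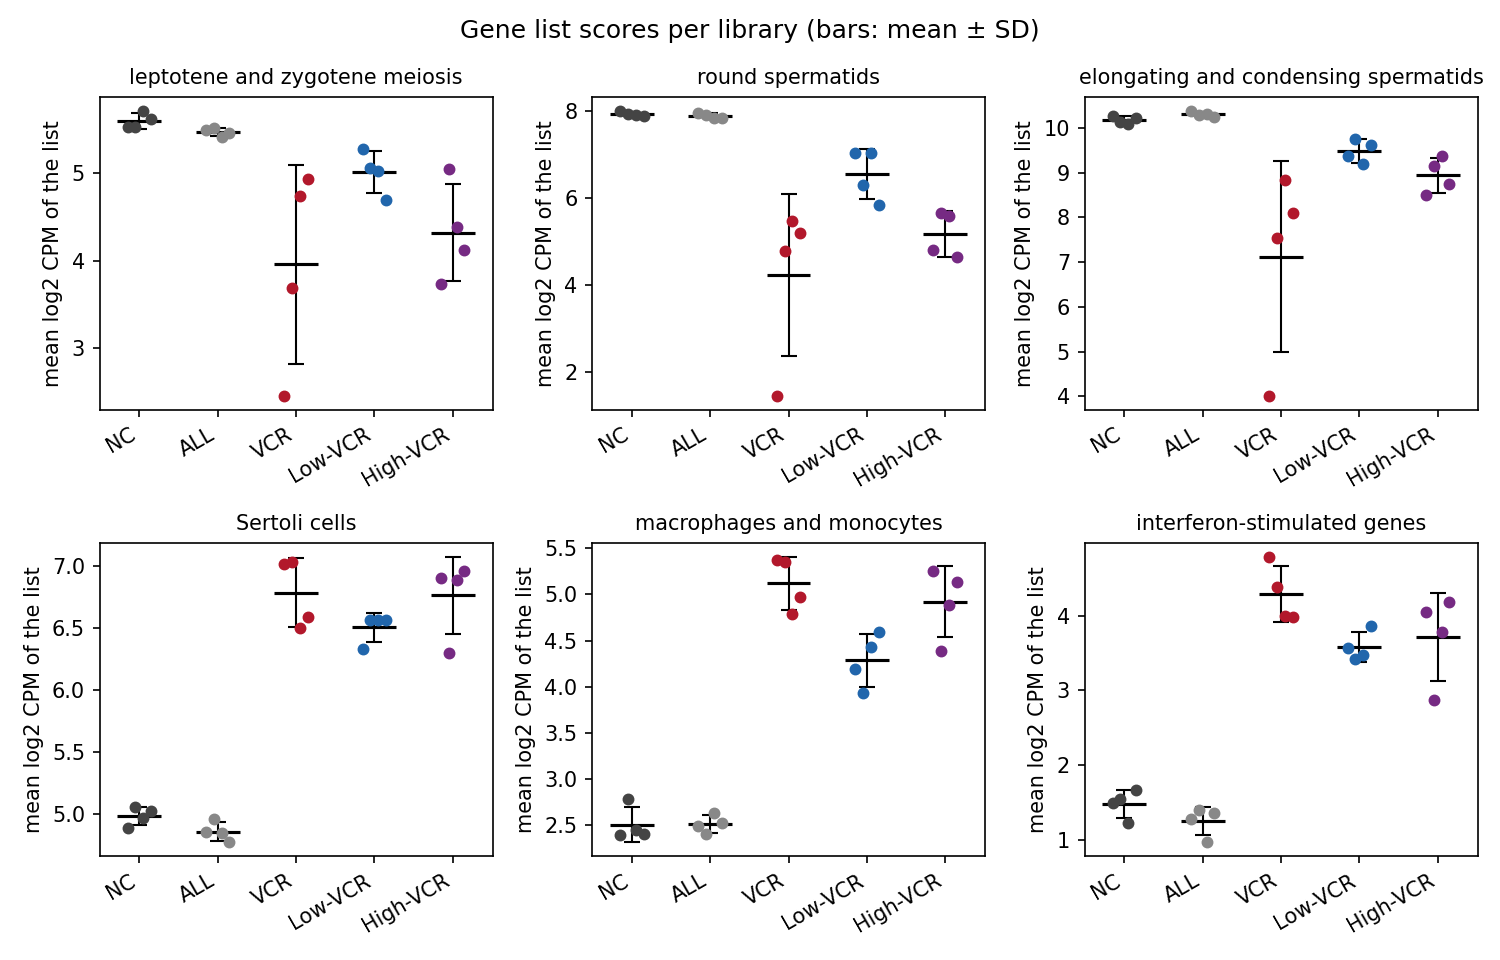
Mean log2 CPM of 6 gene lists in each library (points), with group means ± SD (bars, n = 4). The round spermatid score averages 7.93 in NC, 4.22 in VCR, 6.55 in Low-VCR and 5.17 in High-VCR, while the Sertoli score averages 4.99, 6.78, 6.50 and 6.76; scaling on the Sertoli list removes the Sertoli differences.

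Low-VCR against ALL asks what vincristine did in engrafted mice with low infiltration. Scores of lists of meiotic and later germ cells were lower in Low-VCR with no overlap of the libraries: round spermatids at 5.84 to 7.03 against 7.84 to 7.95 in ALL, pachytene to diplotene spermatocytes at 6.91 to 7.38 against 8.04 to 8.07, the flagellum list at 7.13 to 7.42 against 8.26 to 8.36 and elongating spermatids at 9.18 to 9.76 against 10.23 to 10.38 (mean log2 CPM; exact permutation p 0.0286 each, the smallest possible, adjusted p 0.0335 over 34 lists; a test chosen after the data had been seen). The score of undifferentiated spermatogonia was higher in Low-VCR (1.80 to 2.11 against 1.27 to 1.62, exact permutation p 0.0286), and that of differentiating spermatogonia overlapped (3.61 to 4.50 against 3.83 to 4.00, p 0.4). How many of the meiotic and later genes fell depended on the fit. In the fit of all 5 groups, which shares its spread with the more variable VCR, 6 of 24 round spermatid genes (median -1.16), 3 of 29 leptotene and zygotene genes (-0.46), 2 of 29 flagellum genes (-1.02), 1 of 25 elongating spermatid genes (-0.81), 0 of 22 pachytene genes (-0.90) and 0 of 7 serine kinase genes (-0.95) fell. Adjusted over the list alone, 0 genes of each fell. With only Low-VCR and ALL in edgeR these counts were 22, 12, 26, 24, 20 and 5, in DESeq2 18, 6, 17, 8, 10 and 3, and in limma voom 24, 13, 27, 22, 21 and 7. Catsper1 fell by 1.48 ± 0.42 (adjusted p 0.0074), Izumo1, needed for sperm-egg fusion, by 1.56 ± 0.54 (0.0227), the synaptonemal complex gene Syce3 by 1.09 ± 0.38 (0.0229), the crossover gene Msh4 by 1.51 ± 0.54 (0.0268), Prm3 by 1.31 ± 0.49 (0.0341), Armc2 by 0.89 ± 0.30 (0.0211) and the axonemal gene Cfap44 by 0.94 ± 0.38 (0.0468). Among mitotic genes 1 rose and 3 of 23 fell (median -0.54, 0 adjusted over the list alone; 2 and 14 with only these groups): Mki67 rose by 0.40 ± 0.15 (0.0318) and Ccnb1 fell by 0.77 ± 0.27 (0.0252). The cystatin gene Cst8 fell by 0.56 ± 0.23 (0.0478), while Cst11 rose by 1.91 ± 0.53 (0.0064).

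In the fit of all 5 groups most of these calls in Low-VCR were lost without 1 library. This held for Armc2 and Izumo1 without Low-VCR 2 or 4, for Syce3 without ALL 1 or Low-VCR 4, for Ccnb1 without ALL 2, ALL 3, Low-VCR 2 or Low-VCR 4, and for Msh4 without ALL 4 or Low-VCR 1, 2 or 3. Calls were also lost for Prm3 without any library but ALL 4, for Mki67 without any but Low-VCR 4, for Cst8 without any but Low-VCR 2, and for Cfap44 without any of the 8. The adjusted p was then between 0.0507 (Ccnb1) and 0.123 (Cst8). With library size alone all of these calls except that of Mki67 were lost, while Mki67 was lost in DESeq2 and with its size factors, and with no gene filter Cfap44, Cst8 and Mki67 were lost. Catsper1 and Cst11 kept their calls in these settings.

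Many genes of somatic cell lists rose in Low-VCR. Sertoli cells had 21 of 22 genes higher (median 1.70) and Leydig cells 13 of 15 (1.81). The glutathione transferase Gstm6 rose by 2.37 ± 0.22, the FSH receptor Fshr by 1.96 ± 0.19, the testicular testosterone-forming enzyme Hsd17b3 by 2.82 ± 0.30 and Nr5a1 by 1.74 ± 0.21. Blood-testis barrier junctions (10 of 16 higher, 1.14), peritubular cells (8 of 13 higher, 10 adjusted over the list alone, 1 lower, 1.09), endothelial cells (10 of 15 higher, 11 adjusted over the list alone, 1.49), cholesterol synthesis (12 of 22 higher, 2 lower, 0.75) and extracellular matrix (14 of 21 higher, 1.10) had medians below 0 under Sertoli scaling. The tight junction gene Cldn11 rose by 1.89 ± 0.20, Jam2 by 2.94 ± 0.30, Myl9 by 1.70 ± 0.18, Acta2 by 1.39 ± 0.19, Esam by 1.59 ± 0.19 and Ly6c1 by 2.78 ± 0.34. Ebp and Msmo1, of sterol synthesis, rose by 2.02 ± 0.19 and 2.42 ± 0.29, Timp1 by 3.48 ± 0.32 and the proteoglycan Dcn by 1.89 ± 0.21. Each of these genes had an adjusted p of at most 1.02e-05.

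Most interferon-stimulated, macrophage and inflammatory genes rose in Low-VCR too, while as lists they were not called with an estimated correlation (adjusted p = 0.487). Of 24 interferon-stimulated genes 23 rose (median 2.39), with Psmb8 at 2.68 ± 0.27 and Gbp3 at 3.27 ± 0.33. Of 19 macrophage genes 16 rose and 1 fell (2.23), with C1qa at 2.45 ± 0.22 and C1qc at 2.37 ± 0.23, and of 17 inflammatory genes 13 rose and 2 fell (2.41), with Nfkbia, an inhibitor of NF-kappa B, at 1.65 ± 0.15 and the chemokine Ccl2 at 4.43 ± 0.56. Neutrophil genes rose in 3 of 4 (1.33, below 0 under Sertoli scaling), with Camp at 2.44 ± 0.39 and Csf3r at 1.37 ± 0.27. B lineage and leukocyte genes rose in 3 of 13 (median -0.03, mean 0.34, and median 0.24 with library size alone), with Coro1a at 2.47 ± 0.25 and Mme at 2.05 ± 0.22. Erythroid genes rose in 5 of 7 (2.04), with Alas2 at 1.25 ± 0.20 and Rhd at 2.17 ± 0.43. Their adjusted p was at most 0.000403.

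Of the other lists in Low-VCR, those with medians above 0 here and below 0 under Sertoli scaling were undifferentiated spermatogonia (8 of 14 higher, 1 lower, 0.80), differentiating spermatogonia (4 of 14 higher, 3 adjusted over the list alone, 1 lower, 0.34), p53 targets (15 of 22 higher, 3 lower, 17 and 4 adjusted over the list alone, 1.19), core apoptosis (15 of 22 higher, 16 adjusted over the list alone, 2 lower, 0.97), immediate early genes (8 of 15 higher, 4 lower, 1.57) and NRF2 genes (12 of 19 higher, 13 adjusted over the list alone, 3 lower, 0.51). The same held for glucocorticoid-induced (9 of 14 higher, 2 lower, 1.08), hypoxia-induced (11 of 18 higher, 2 lower, 1.12), mitochondrially encoded (12 of 13 higher, 13 adjusted over the list alone, mean 1.29), cytosolic ribosomal protein (20 of 44 higher, 3 lower, 0.26) and adipocyte genes (1 of 6 higher, 0.30). Heat shock genes (8 of 21 higher, 3 lower) had a median of -0.21, a mean of 0.32 and a median of 0.05 with library size alone, and tubulins (5 of 15 higher, 5 lower) a median of -0.72 and a mean of 0.14. Etv5, of spermatogonial self-renewal, rose by 1.00 ± 0.14, Tspan8 by 2.19 ± 0.38, Kit by 1.42 ± 0.24 and Ccnd2 by 1.24 ± 0.29. Ccng1 rose by 1.97 ± 0.23, Sesn2 by 1.35 ± 0.16, Birc3 by 2.42 ± 0.18, Casp6 by 1.57 ± 0.15, Ier2 by 1.84 ± 0.19 and Junb by 2.05 ± 0.25. G6pdx rose by 2.12 ± 0.19, Gsta4 by 2.38 ± 0.24, Sult1a1 by 2.21 ± 0.23, Ddit4 by 1.58 ± 0.17, Ndrg1 by 1.69 ± 0.19 and Ero1a by 1.07 ± 0.13. Tubb5 rose by 1.75 ± 0.22, Tubb3 by 1.77 ± 0.23, Hspb1 by 1.58 ± 0.18, Hspd1 by 1.74 ± 0.22 and Plin4 by 2.10 ± 0.48. mt-Co3 rose by 1.46 ± 0.25, mt-Co2 by 1.48 ± 0.26, Rpl14 by 1.06 ± 0.17 and Rpl10a by 0.87 ± 0.15. The adjusted p of these genes was at most 0.00212.

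Genes listed at 0 in all 4 ALL libraries led the rises in Low-VCR: Pi4ka was at 71.9 ± 66.1 CPM (SD, n = 4; at least 927-fold higher), Insc at 3.19 ± 0.348 (40.7-fold), Itih4 at 2.58 ± 1.31 (33-fold), the Hippo pathway factor Tead1 at 2.29 ± 0.901 (29.6-fold), Wfdc18 at 1.92 ± 0.819 (24.2-fold) and Cd72 at 1.12 ± 0.611 (14.7-fold). Gfi1b, an erythroid and megakaryocyte transcription factor, was at 1.31 ± 0.228 CPM in ALL and listed at 0 in Low-VCR (at least 24.6-fold lower). Slc2a9 fell by 3.13 ± 0.92 (-3.84 without Low-VCR 1), Frat2 by 3.05 ± 0.50, Krtap17-1 by 2.96 ± 0.78, Dmrta2 by 2.77 ± 0.71 (-3.45 without Low-VCR 1) and the oligodendrocyte factor Olig2 by 2.7 ± 0.63. Each of these genes had an adjusted p of at most 0.0114. Pi4ka was also listed at 0 in NC 1 and NC 2 and had 1280 counts in NC 4, and limma voom did not call it for Low-VCR.

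In total 8527 genes passed for Low-VCR relative to ALL, 6016 higher and 2511 lower (70.6% higher; 3874 and 870 among those changed at least 2-fold). The split was 5080 to 4525 with DESeq2 size factors (52.9%), 5150 to 5098 in DESeq2 (50.3%), 7239 to 870 with library size alone (89.3%), 5976 to 4768 with only these groups (55.6%), 6546 to 5624 in limma voom and 560 to 12617 under Sertoli scaling (4.25%). With the library number range as a covariate 9602 passed, 5924 higher and 3678 lower. The median of all genes moved by 0.26 with library size alone, -0.17 with DESeq2 size factors and -1.64 under Sertoli scaling. Camera called 14 lists up and 6 down, and 0 with an estimated correlation (adjusted p 0.487 to 0.733). The list calls were lost for elongating spermatids with DESeq2 size factors (adjusted p 0.0806), and for hypoxia-induced genes with library size alone (0.0626) and without ALL 1 (adjusted p 0.0503), Low-VCR 3 (0.0524) or Low-VCR 4 (0.0615), for leptotene and zygotene genes without Low-VCR 4 (0.0688) and for mitotic genes without Low-VCR 3 (0.0524). Under Sertoli scaling Camp, Ccng1, Cldn11, Cst11, Dcn, Fshr, Hspd1, Ier2, Junb, Myl9, Ndrg1, Nfkbia, Nr5a1, Plin4, Rhd, Tspan8, Tubb3 and Tubb5 no longer passed, and the sign of Acta2, Alas2, Casp6, Ccnd2, Csf3r, Ddit4, Ero1a, Esam, Etv5, Hspb1, Kit, Mki67, Sesn2, mt-Co2, mt-Co3, Rpl10a and Rpl14 turned.

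High-VCR against ALL asks what vincristine did in engrafted mice with high infiltration. Late germ cell genes fell: 23 of 24 round spermatid genes (median -2.24), 12 of 25 elongating spermatid genes (10 adjusted over the list alone, 25 with only these groups in edgeR, -1.28), 6 of 7 serine kinase genes (-1.61) and 18 of 29 flagellum genes (-1.39). Catsper1 fell by 3.39 ± 0.45, Catsper3 by 4.19 ± 0.59, Prm3 by 1.98 ± 0.50, Ropn1 by 1.90 ± 0.50, Tssk5 by 4.39 ± 0.76, Tekt2 by 3.22 ± 0.56 and Tekt4, another tektin, by 3.18 ± 0.61. Of the meiotic lists 11 of 29 leptotene and zygotene genes (9 adjusted over the list alone, 22 with only these groups, -1) and 10 of 22 pachytene genes (3 adjusted over the list alone, 16 with only these groups, -1.24) fell, with Rec8 at -3.29 ± 0.50, Syce3 at -2.10 ± 0.39, Cdc25c at -1.60 ± 0.30 and Calr3 at -1.84 ± 0.39. Mitotic genes fell in 12 of 23 and rose in 1 (9 and 0 adjusted over the list alone, -0.76), with Ccnb1 at -1.54 ± 0.28 and the kinesin Kif23 at -1 ± 0.19. Differentiating spermatogonia had 3 of 14 genes higher and 5 lower (-0.60), and undifferentiated ones 8 of 14 higher (7 adjusted over the list alone, 0.80, below 0 under Sertoli scaling). Kit rose by 2.69 ± 0.25, Ccnd2 by 2.00 ± 0.29, Etv5 by 1.33 ± 0.14 and Tspan8 by 3.19 ± 0.38. Their adjusted p was at most 0.00282.

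Most genes of the Sertoli, Leydig, macrophage, interferon and inflammatory lists rose in High-VCR, while as lists they were not called with an estimated correlation (adjusted p = 0.545). Sertoli cells had 21 of 22 genes higher (22 adjusted over the list alone, median 1.99), Leydig cells 14 of 15 (2.40), macrophages 17 of 19 with 1 lower (2.67), interferon-stimulated genes 23 of 24 (2.53) and inflammatory genes 14 of 17 with 2 lower (3.37). Shbg rose by 2.69 ± 0.22, Gstm6 by 2.64 ± 0.22, Hsd17b3 by 3.55 ± 0.30 and Nr5a1 by 2.40 ± 0.21. C1qa rose by 2.81 ± 0.23, Lyz2 by 2.86 ± 0.24, Gbp2 by 3.33 ± 0.30, Psmb8 by 3.02 ± 0.27, Nfkbia by 1.95 ± 0.15 and Serpina3n by 3.49 ± 0.34. Blood-testis barrier junctions (11 of 16 higher, 2 lower, 1.43), peritubular cells (11 of 13 higher, 1 lower, 1.54), endothelial cells (13 of 15 higher, 1.80), cholesterol synthesis (17 of 22 higher, 3 lower, 4 lower adjusted over the list alone, 1.37), extracellular matrix (16 of 21 higher, 2 lower, 1.47), neutrophils (4 of 4 higher, 1.81) and B lineage genes (5 of 13 higher, 2 lower, 0.21) had medians below 0 under Sertoli scaling. F11r rose by 2.10 ± 0.18, Jam2 by 3.51 ± 0.31, Myl9 by 1.93 ± 0.18, the muscle filament gene Des by 1.67 ± 0.19, Kdr by 2.80 ± 0.24, Esam by 1.96 ± 0.19, Ebp by 2.16 ± 0.19 and Msmo1 by 3.07 ± 0.30. Timp1 rose by 3.98 ± 0.32, Sparc by 2.25 ± 0.20, Camp by 2.62 ± 0.39, Csf3r by 1.59 ± 0.26, Mme by 2.80 ± 0.23 and Coro1a by 2.46 ± 0.25. Erythroid genes rose in 5 of 7 and fell in 1 (2.00), with Alas2 at 1.65 ± 0.20 and Hbb-bs at 2.79 ± 0.47. The adjusted p of these genes was at most 4.62e-05.

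Further lists in High-VCR had medians above 0 that fell below 0 under Sertoli scaling: p53 targets (17 of 22 higher, 4 lower, 1.66), core apoptosis (17 of 22 higher, 2 lower, 1.40), immediate early genes (8 of 15 higher, 4 lower, 1.85), NRF2 genes (12 of 19 higher, 3 lower, 0.92), glucocorticoid-induced genes (9 of 14 higher, 2 lower, 3 lower adjusted over the list alone, 1.41) and hypoxia-induced genes (12 of 18 higher, 2 lower, 1.49). The same held for mitochondrially encoded genes (13 of 13 higher, 1.56), ribosomal protein genes (23 of 44 higher, 4 lower, 0.37), adipocytes (2 of 6 higher, 1 lower, 0.37) and heat shock genes (9 of 21 higher, 8 lower, 0.03, also below 0 with DESeq2 size factors). Tubulins had 5 of 15 higher and 8 lower (-1.22), and epididymis genes 1 of 3 higher and 2 lower (-1.09). Ccng1 rose by 2.65 ± 0.23, Sesn2 by 1.67 ± 0.16, Birc3 by 2.83 ± 0.18, Casp6 by 1.90 ± 0.15, Ier2 by 2.12 ± 0.19 and Junb by 2.40 ± 0.25. G6pdx rose by 2.47 ± 0.19, Gsta4 by 2.67 ± 0.24, Ddit4 by 1.99 ± 0.17, Sult1a1 by 2.7 ± 0.23, Ero1a by 1.41 ± 0.13 and Ndrg1 by 1.96 ± 0.19. Tubb5 rose by 2.04 ± 0.22, Tubb3 by 2.06 ± 0.23, Hspb1 by 2.08 ± 0.18, Hspd1 by 2.14 ± 0.22, mt-Co3 by 1.67 ± 0.25, mt-Nd1 by 1.92 ± 0.30, Rps4x by 1.43 ± 0.18 and Rpl10a by 1.13 ± 0.15. Adipoq, the adiponectin gene, fell by 2.72 ± 0.59 while Plin4 rose by 2.23 ± 0.48, and Cst8 fell by 1.09 ± 0.23 while Cst11 rose by 1.67 ± 0.53. Each of these genes had an adjusted p of at most 0.00968.

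Genes listed at 0 in all 4 ALL libraries led the rises in High-VCR: Nckap5 was at 20.5 ± 7.06 CPM (SD, n = 4; at least 266-fold higher), Tead1 at 4.56 ± 3.27 (58.8-fold), Wfdc18 at 4.07 ± 2.54 (53.2-fold), Insc at 3.54 ± 1.61 (46.5-fold), Itih4 at 3.31 ± 0.907 (43-fold) and the cytokine gene Lif at 2.23 ± 0.519 (28.5-fold). Listed at 0 in all 4 High-VCR libraries were Myt1 (6.04 ± 3.95 CPM in ALL, at least 126-fold lower), Umodl1 (5.74 ± 1.4, 120-fold), Pcdh10 (4.67 ± 2.49, 99-fold) and Commd1b (4.16 ± 2.13, 86.3-fold). Dpp6 had 503 counts in ALL and 1 in High-VCR, in High-VCR 3, a ratio of 830 (95% interval 148 to 32800; listed at 0 without High-VCR 3, at least 210-fold lower; not called by limma voom). Its counts also varied within groups, with 1 in ALL 1 against 149 to 180 in the other ALL libraries, and 165 in NC 2 against 0 to 2 in the other NC libraries. Pacs2 fell from 328 ± 25.9 to 4.09 ± 5.13 CPM (-6.33 ± 1.31, and -7.44 without High-VCR 2). Their adjusted p was at most 0.00382.

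Altogether 12054 genes passed for High-VCR relative to ALL, 7015 higher and 5039 lower (58.2% higher), against 8137 and 3724 with library size alone (68.6%) and 935 and 12452 under Sertoli scaling (6.98%). The split was close to even in DESeq2 (6347 and 6203) and with its size factors (6295 and 6031), and turned with only these groups (5825 higher, 6118 lower). With the library number range as a covariate 12183 passed. The median of all genes moved by 0.29 with library size alone, -0.18 with DESeq2 size factors and -1.87 under Sertoli scaling. Camera called 15 lists up and 7 down, and 0 with an estimated correlation (adjusted p 0.545 to 0.647). The calls were lost for cholesterol synthesis without High-VCR 1 (0.0564), for serine kinases without High-VCR 2 (0.0733) or with DESeq2 size factors (0.0737) and for hypoxia-induced genes with library size alone (0.0564). Under Sertoli scaling Camp, Ccnd2, Ddit4, Ebp, Esam, F11r, Hbb-bs, Hspb1, Hspd1, Ier2, Junb, Myl9, Ndrg1, Nfkbia, Plin4, Tubb3 and Tubb5 no longer passed, and the sign of Alas2, Casp6, Csf3r, Cst11, Des, Ero1a, Etv5, Sesn2, mt-Co3, mt-Nd1, Rpl10a and Rps4x turned.

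The responses to vincristine with and without engraftment were compared across 16534 genes, which are not independent replicates. The changes of VCR against NC and High-VCR against ALL, which share no library, had r = 0.94 (Spearman's rho 0.97): 6506 genes were called higher in both, 4807 lower in both and 3 in opposite directions, where independent lists would share 2953 and 1795. For VCR against NC and Low-VCR against ALL, r was 0.88 (rho 0.94), with 5731 genes higher in both, 2336 lower in both and 6 opposite, where independent lists would share 2532 and 895. The SD of the changes was 0.61 times that of VCR in Low-VCR and 0.88 times in High-VCR. Low-VCR and High-VCR against the shared ALL libraries had r = 0.93 (rho 0.96), with 5922 genes higher in both, 2329 lower in both and 0 opposite, where independent lists would share 2552 and 765. Unchanged groups simulated 20 times against the same controls gave a mean r of 0.53 and at most 0.56, and the 6 splits of the ALL libraries gave 0.86 to 0.87. The covariance was 1.66 against a simulated 0.10, a difference of 1.56.

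High-VCR against Low-VCR asks about infiltration among treated mice. Round spermatid genes were lower in High-VCR in 9 of 24 (11 adjusted over the list alone, median -1.05) and leptotene and zygotene genes in 4 of 29 (6 adjusted over the list alone, -0.54). Catsper3 fell by 2.76 ± 0.56, Catsper1 by 1.91 ± 0.43, the meiotic recombinase Dmc1 by 2.39 ± 0.48, Rec8 by 2.14 ± 0.48, Tssk5 by 3.17 ± 0.73 and the testis protease Prss50 by 2.42 ± 0.61. Kit was higher by 1.28 ± 0.23. Leydig genes were higher in 4 of 15 (6 adjusted over the list alone, median 0.50), with Hsd3b1 at 1.18 ± 0.27 and the Leydig hormone Insl3 at 1.15 ± 0.32, and endothelial genes in 2 of 15 (3 adjusted over the list alone, 0.37), with Kdr at 0.98 ± 0.22 and Plvap at 1.64 ± 0.43. Of the inflammatory genes 2 of 17 were higher (5 adjusted over the list alone, 0.80), with Cebpd at 1.27 ± 0.33 and Serpina3n at 1.02 ± 0.30. Btbd6 led the rises (3.01 ± 0.86, and 4.02 without Low-VCR 4), followed by Ankrd63 (2.25 ± 0.47) and Stk32a (1.76 ± 0.47). Umodl1 was at 2.40 ± 1.06 CPM in Low-VCR (SD) and listed at 0 in High-VCR (at least 51.5-fold lower), and Dpp6 had 350 counts against 1, in High-VCR 3, a ratio of 392 (95% interval 69.8 to 15500; listed at 0 without High-VCR 3, at least 99.2-fold lower, adjusted p 0.0834). Within Low-VCR, Low-VCR 4 had 1 count of Dpp6 and the others 96 to 140, and NC 1, NC 3 and NC 4 had 0 to 2. The adjusted p of these genes was at most 0.0466.

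For High-VCR relative to Low-VCR 1292 genes passed, 517 higher and 775 lower (40% higher; 99 and 645 among those changed at least 2-fold), against 289 and 804 with the upper quartile (26.4%) and 58 and 932 under Sertoli scaling (5.86%), which moved the median of all genes by -0.23. No gene passed without High-VCR 1, High-VCR 4, Low-VCR 1 or Low-VCR 3, in edgeR with only these groups, or with only the 12 treated libraries, and 3218 passed without High-VCR 2, where the majority turned (2083 higher, 1135 lower). At an unadjusted p under 0.05 there were 4570 genes, and DESeq2 called 2137 (930 higher, 1207 lower) and limma voom 8419 (4440 higher, 3979 lower). With the library number range as a covariate 1691 passed. The round spermatid score was higher in Low-VCR by 1.44 and 1.32 within the ranges and 1.38 pooled. Camera called 8 lists up and 7 down, and 0 with an estimated correlation (adjusted p 0.649 to 0.776). Without single libraries calls were lost for elongating spermatids (High-VCR 1 and 4, Low-VCR 2 and 4; adjusted p 0.0729 to 0.3; also with DESeq2 size factors, 0.0511), pachytene genes (High-VCR 1, 3 and 4, Low-VCR 2 and 4; 0.0584 to 0.242), differentiating spermatogonia (High-VCR 4, Low-VCR 1 and 3; 0.0557 to 0.0763) and Sertoli cells (High-VCR 1, 3 and 4, Low-VCR 1; 0.0727 to 0.0767). The same held for p53 targets (High-VCR 1 and 4; 0.0645 to 0.0767), extracellular matrix (High-VCR 1, Low-VCR 2; 0.0767 to 0.138) and mitotic genes (High-VCR 1; 0.0844).

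Low-VCR was also compared with VCR. Among spermatid and meiotic lists, genes called were higher in Low-VCR: 20 of 25 elongating spermatid genes (25 adjusted over the list alone, median 1.66), 13 of 24 round spermatid genes (16 adjusted over the list alone, 1.71), 6 of 7 serine kinase genes (7 adjusted over the list alone, 1.82), 7 of 29 flagellum genes (7 adjusted over the list alone, 1.01), 3 of 22 pachytene genes (3 adjusted over the list alone, 0.71) and 7 of 29 leptotene and zygotene genes (10 adjusted over the list alone, 0.74). Catsper3 was higher by 3.19 ± 0.58, Rec8 by 2.64 ± 0.50, Cdc25c by 1.73 ± 0.31, Ropn1 by 2.01 ± 0.51, Tssk5 by 4.52 ± 0.82 and Tekt2 by 2.32 ± 0.54. Spermatogonial genes went both ways: 6 of 14 differentiating genes were higher and 2 lower (8 and 2 adjusted over the list alone, 0.74), and 1 of 14 undifferentiated genes was higher and 1 lower (1 and 1 adjusted over the list alone; median -0.17, mean 0.05). Kit (-1.30 ± 0.23), Ccnd2 (-1.28 ± 0.26) and Tspan8 (-1.12 ± 0.32, adjusted p 0.0176; 0.0706 without VCR 1) were lower in Low-VCR. Lower in Low-VCR were also 12 of 15 Leydig genes (13 adjusted over the list alone, -0.83), 14 of 19 macrophage genes with 1 higher (16 adjusted over the list alone, -0.74), 13 of 24 interferon-stimulated genes (15 adjusted over the list alone, -0.75) and 12 of 21 matrix genes with 1 higher (15 adjusted over the list alone, -0.67). Nr5a1 was lower by -1.04 ± 0.20, Sc5d by -1.45 ± 0.33, Kdr by -1.24 ± 0.22, Fcgr1 by -1.48 ± 0.29, Ifi27l2a by -1.29 ± 0.27, C3 by -1.38 ± 0.31 and Col4a2 by -0.98 ± 0.19, while Aif1 was higher by 1.58 ± 0.28. Etfbl was at 1.66 ± 1.11 CPM (SD) and listed at 0 in VCR (at least 30.9-fold higher), and Btbd35f15 had 211 counts against 1, in VCR 2, a ratio of 204 (95% interval 36.2 to 8100; VCR listed at 0 without VCR 2, at least 51.6-fold higher). Each of these genes except Tspan8 had an adjusted p of at most 0.01.

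For Low-VCR relative to VCR 5000 genes passed, 2757 higher and 2243 lower (55.1% higher), and 2030 and 349 among those changed at least 2-fold, against 2515 and 4081 with library size alone (38.1%), 2632 and 4152 with the upper quartile (38.8%) and 2596 and 528 under Sertoli scaling (83.1%), which moved the median of all genes by -0.15, -0.16 and 0.26. Without Low-VCR 1, VCR 1 or VCR 2, 2960, 3072 and 2483 genes passed. With only the 12 treated libraries 924 passed, and with only these groups 1. Camera called 7 lists up and 12 down, and 0 with an estimated correlation (adjusted p 0.464). Calls were lost for NRF2 genes (median -0.46) without Low-VCR 1 or 3 or VCR 1 or 2 (adjusted p 0.0524 to 0.0816) and with a filter of 1 CPM in 4 samples (0.0528), for Sertoli cells (-0.35) without VCR 2 (0.0592) and for core apoptosis (-0.34) without Low-VCR 1 (0.0546) or VCR 2 (0.0509).

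High-VCR and VCR differed in 1 gene, Btbd35f15, a member of a family of near-identical copies. It had 124 counts in High-VCR and 1 in VCR, in VCR 2, a ratio of 107 (95% interval 18.9 to 4270; adjusted p 0.00212). Without VCR 2, VCR was listed at 0 (at least 27.1-fold higher in High-VCR, adjusted p 0.0204), and the call was lost in limma voom (0.0965) and with only these groups (0.178). Nupr1l (2.46 ± 0.48) and Hgh1 (0.50 ± 0.10), next by p, did not pass (adjusted p 0.299). Elongating spermatid genes had a median of 1.12 and interferon-stimulated genes of -0.54, with 0 genes of either called (1 interferon-stimulated gene lower, adjusted over the list alone). At an unadjusted p under 0.05 there were 1358 genes, DESeq2 called 34 and limma voom 0, and edgeR with only these groups 0. Without VCR 2, VCR 3 or VCR 4, 2, 3 and 3 genes passed. Camera called 6 lists up and 8 down, and 0 with an estimated correlation (adjusted p 0.525 to 0.782). Without High-VCR 2 or VCR 1 the calls were lost for round spermatids (median 0.43; adjusted p 0.0866 and 0.944), pachytene (0.44; 0.462 and 0.946), flagellum (0.45; 0.262 and 0.944), mitotic (0.29; 0.763 and 0.905), macrophage (-0.31; 0.129 and 0.0648), endothelial (-0.23; 0.38 and 0.134) and p53 target genes (-0.18; 0.38 and 0.153). Without VCR 2 they were lost for mitotic (0.26) and endothelial genes (0.0639). Library size alone and the upper quartile moved the median of all genes by -0.11 and -0.14.

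Whether the response to vincristine differed in engrafted mice was tested by interaction, with the sorting of treated mice on infiltration as part of each test. For Low-VCR 839 genes passed, 630 with a more positive change than in VCR against NC and 209 with a more negative one (75.1% more positive; 62.2% with library size alone, 61% with the upper quartile and 64.3% under Sertoli scaling). The gene with the smallest p was Btbd35f15 (adjusted p 0.000887), with 249 counts in NC, 171 in ALL, 211 in Low-VCR and 1 in VCR. Its ratio of ratios of summed counts was 277 (95% interval 49.7 to 10900, for the VCR count alone; at least 70.1 without VCR 2, where VCR was listed at 0). It was followed by the islet cell autoantigen Ica1 (2.09 ± 0.30, adjusted p 0.0144) and Serpina3n (-3.33 ± 0.49, adjusted p 0.0144), which was at 1.22 ± 0.489 CPM in NC, 5.22 ± 1.93 in ALL, 69.7 ± 22.2 in VCR and 28.9 ± 3.6 in Low-VCR (SD, n = 4). The count was 7 without ALL 2 or Low-VCR 1, 8 without ALL 3, 10 without Low-VCR 3, 11 without ALL 4, 18 without NC 1, 22 without NC 3, 53 without ALL 1, 80 without VCR 2, 138 without NC 4, 179 without NC 2, 1291 without VCR 1, 1407 without Low-VCR 4 and 2322 without VCR 3. For High-VCR 1 gene passed, again Btbd35f15 (adjusted p 0.00924), with 752 genes at an unadjusted p under 0.05, 5 called by DESeq2 and 3 by limma voom. With 124 counts in High-VCR and 1 in VCR its ratio of ratios was 146 (95% interval 26.1 to 5750, for the VCR count alone; at least 36.8 without VCR 2), and the call was lost in limma voom (adjusted p 0.116) and with only these groups (0.068). Without ALL 3, ALL 4, NC 4, VCR 3 or VCR 4, 2 genes passed.

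By list, the interaction of Low-VCR was positive for round spermatids (median 1.65), elongating spermatids (1.54) and leptotene and zygotene genes (0.83), and negative for inflammatory (-1.11), macrophage (-0.86) and extracellular matrix genes (-0.78). Camera called 7 lists up and 11 down for it, and 0 with an estimated correlation (adjusted p 0.557 to 0.619). Calls were lost for NRF2 genes without Low-VCR 3, NC 3, VCR 1 or VCR 2 (adjusted p 0.0567 to 0.0799) and for cholesterol synthesis without VCR 2 (0.0593). For High-VCR camera called 6 lists up and 10 down, such as elongating spermatids (0.99) and ribosomal proteins (-0.20), and 0 with an estimated correlation (adjusted p 0.512 to 0.772). Without High-VCR 2, calls for High-VCR were lost for round spermatids (0.185), pachytene (0.603), flagellum (0.489), serine kinase (0.0537), mitotic (0.732), Leydig (0.165), cholesterol synthesis (0.0734), macrophage (0.0536), B lineage (0.0709), interferon-stimulated (0.096) and p53 target genes (0.422). Without VCR 1 they were lost for round spermatids (0.945), pachytene (0.966), flagellum (0.945), mitotic (0.701), Leydig (0.129), cholesterol synthesis (0.215), interferon-stimulated (0.0764) and p53 target genes (0.385). Without VCR 2 they were lost for pachytene (0.101), mitotic (0.13), cholesterol synthesis (0.26) and p53 target genes (0.0607), without High-VCR 3 for cholesterol synthesis (0.0822), and without ALL 1, NC 1 or NC 4 for p53 targets (0.0561, 0.0685 and 0.0622).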

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

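The tests chosen only after results were seen are those of the percentile and scaling of Tssk4 and Ccdc159, of list scores with and without the Sertoli score or another somatic score, of the round spermatid score without VCR 1, and of the shared spread.

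A library lay far from the other 3 of its group in 3 of 60 groups of scores tested, where chance alone would mark about 1 in 20 groups, or 3. The Sertoli score was 6.33 in Low-VCR 1 and 6.56 in the other Low-VCR libraries, and 6.30 in High-VCR 2 against 6.88 to 6.96 in the others. The macrophage and monocyte score was 2.78 in NC 2 and 2.39 to 2.44 in the other NC libraries.

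The response to vincristine differed between engrafted and other mice by the interaction test in 839 genes for Low-VCR, among them Ica1 (2.09 ± 0.30) and Serpina3n (-3.33 ± 0.49), log2 ± standard error in edgeR, and Btbd35f15. For High-VCR it differed in 1 gene, again Btbd35f15. The fitted values of Btbd35f15, 7.39 and 6.46, rest on 1 count in VCR and depend on the prior count; as ratios of ratios of summed counts they were 277 (95% interval 49.7 to 10900, for the VCR count alone) and 146 (26.1 to 5750). Of 100 groupings only the real one called 839 genes. The next (465, 296 and 221) kept Low-VCR and VCR whole, so a changed response cannot be told from a difference between those groups. The count of 839 is fragile: leaving out 1 library gave 7 (without ALL 2 or Low-VCR 1) to 2322 (without VCR 3). For the High-VCR interaction 17 of 100 called at least as many, so chance cannot be excluded there.

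The same libraries were also split in all 35 ways for each pairwise comparison. For High-VCR against VCR 6 of 35 called at least as many genes as the real 1, so chance cannot be excluded there. For ALL against NC edgeR called 0 genes (748 at an unadjusted p under 0.05; DESeq2 19, limma voom 104), which each of the 35 splits must reach (highest other 2), so that count tests nothing. The highest other split of High-VCR and VCR, with VCR 1 and 2 and High-VCR 1 and 4 against the rest, called 6350 genes, which shows structure among the samples that the labels do not name. Only 1 split, the real one, reached the count for VCR against NC (12851, highest other 1), Low-VCR against ALL (8527, highest other 0), High-VCR against ALL (12054, highest other 3384), High-VCR against Low-VCR (1292, highest other 849) and Low-VCR against VCR (5000, highest other 1043). With only the compared libraries in the edgeR fit, 1 gene passed for Low-VCR against VCR and 0 for High-VCR against Low-VCR, so those counts may rest on the spread estimate shared with the less variable untreated groups.

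Tssk4 and Ccdc159 were lower in VCR than in NC. If fewer spermatids lowered all spermatid transcripts alike, both should lie within the changes of the 49 genes of the round and elongating spermatid lists (median -2.42, 5th percentile -4.38, 95th -1.75). Ccdc159 lay at percentile 22.4 and Tssk4 at 4.08, within its standard error of 0.73 of that range. As the 49 genes did not fall alike, fewer spermatids are neither shown nor excluded. Scaling of the libraries is excluded as the cause, since the change closest to 0 under 4 other scalings, with library size alone, was -4.30 for Tssk4 and -2.88 for Ccdc159. An effect of the drug on the transcription of either gene was not tested.

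Macrophage and interferon-stimulated genes were higher in VCR than in NC. A lower share of germ cells may raise other cell types alike, measured here by the Sertoli score. The macrophage score rose over the Sertoli score by 0.82 (larger SD 0.15, n = 4, exact permutation p 0.0286). The interferon score rose over Sertoli by 1.02 (larger SD 0.19, exact permutation p 0.0286), the smallest p possible. Immune cells were not alone in this: over Sertoli, endothelial (0.68) and Leydig scores (0.51) rose too and peritubular scores fell (-0.73), and macrophage and interferon scores exceeded endothelial ones by only 0.14 (larger SD 0.34) and 0.34 (larger SD 0.33, exact permutation p 0.143). Reads of human leukaemia cells counted on mouse genes are unlikely as the cause, since the scores rose by 2.61 (SD 0.29) and 2.81 (SD 0.38) in VCR, whose labels name no injected cells. A rise of the immune scores beyond that of endothelial cells is not shown, and a loss of germ cells alone is not excluded. Cell numbers or transcripts per cell may underlie each score.

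The round spermatid score was higher in Low-VCR than in VCR by 2.33 (larger SD 1.87, n = 4, exact permutation p 0.0286) and, without the strongly depleted VCR 1, by 1.41 (larger SD 0.58, exact permutation p 0.0571). The remaining VCR libraries (4.77 to 5.47) did not overlap Low-VCR (5.84 to 7.03), which argues against that single library as the whole cause, though it adds to the size; this was judged by spread and overlap after the p had been seen. Low-VCR and VCR share 0 library number ranges, so the range cannot be told apart from the group. Low-VCR and High-VCR share both ranges, and the score was higher in Low-VCR by 1.44 and 1.32 within them (pooled 1.38, larger SD 0.58, exact permutation p 0.0286), which excludes the range as the cause. VCR, with no leukaemia cells named, scored 4.22 (5.14 without VCR 1) beside 5.17 in High-VCR, which was higher by 0.95 with an exact permutation p of 0.457, so whether the score goes with infiltration stays open.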

How the results depend on the processing

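Calls of named genes mostly kept their direction and side of the threshold: 352 of those tested did with DESeq2 size factors, 346 with DESeq2, 343 with library size alone, 350 with the upper quartile, 356 with a filter of 1 CPM in 4 samples and 334 with limma voom. Fits of only the groups compared lost 106 calls and kept 236, and fits of only the 12 treated libraries lost 71 and kept 42. With an estimated correlation 147 list calls were lost. Depth sets the floor: 3 counts correspond to 0.167 to 0.365 CPM in a single library. Scaling on the Sertoli list and the fit of only the 12 treated libraries were chosen after seeing the data. That scaling makes Sertoli transcripts equal by construction. The cause of the other changes listed here was not tested.

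Sertoli scaling turned the sign of 40 named changes. In VCR against NC these were Acta2 -0.07, Alas2 -0.57, Csf3r -0.25, Cst11 -0.41, Foxo1 -0.29, mt-Co3 -0.30, mt-Nd4l -0.07, Myl9 0, Rps19 -0.12, Rps3 -0.22, Sesn2 -0.09. In Low-VCR against ALL they were Acta2 -0.26, Alas2 -0.41, Casp6 -0.07, Ccnd2 -0.39, Csf3r -0.27, Ddit4 -0.06, Ero1a -0.56, Esam -0.05, Etv5 -0.65, Hspb1 -0.07, Kit -0.21, Mki67 -1.22, mt-Co2 -0.16, mt-Co3 -0.18, Rpl10a -0.77, Rpl14 -0.58, Sesn2 -0.29. In High-VCR against ALL they were Alas2 -0.27, Casp6 -0.02, Csf3r -0.30, Cst11 -0.23, Des -0.24, Ero1a -0.50, Etv5 -0.58, mt-Co3 -0.25, mt-Nd1 -0.02, Rpl10a -0.76, Rps4x -0.48, Sesn2 -0.26.

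Counts of called genes changed. For ALL against NC (0), DESeq2 called 19, limma voom 104, the fit of only these groups 28 and Sertoli scaling 4, and leaving out 1 library gave 0 to 2. For Low-VCR against ALL (8527), 4744 also changed at least 2-fold and Sertoli scaling called 13177. For High-VCR against Low-VCR (1292), DESeq2 called 2137 and limma voom 8419, 744 also changed at least 2-fold, the fits of only these groups and of the 12 treated libraries called 0 each, and leaving out 1 library gave 0 to 3218. For Low-VCR against VCR (5000), 2379 also changed at least 2-fold, the fit of the 12 treated libraries called 924, that of only these groups 1 and Sertoli scaling 3124, and leaving out 1 library gave 2483 to 6975. For High-VCR against VCR (1), DESeq2 called 34, limma voom 0 and the fit of only these groups 0, and leaving out 1 library gave 1 to 3. For the Low-VCR interaction (839), DESeq2 called 1868, limma voom 2603, library size alone 513 and Sertoli scaling 244, and leaving out 1 library gave 7 to 2322. For the High-VCR interaction (1), DESeq2 called 5, limma voom 3 and the fit of only these groups 0, and leaving out 1 library gave 1 to 2.

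Ccdc159 in High-VCR against ALL (-1.38) passed with the library number range as a covariate (-1.41, adjusted p 0.0188), limma voom (-1.51, 0.00344), only the groups compared (-1.66, 0.00986), Sertoli scaling (-3.34, 0.00311) and without High-VCR 3 (-2.04, 0.0491); leaving out 1 library gave -2.04 to -1.07. In Low-VCR against ALL (-0.19) it turned to 0.06 with library size alone and to 0.12 without ALL 1, with a range of -0.42 to 0.12. Tssk4 in Low-VCR against ALL (-1.20) passed with limma voom (-1.15, 0.00528) and Sertoli scaling (-2.81, 0.00209). The r of VCR against NC with High-VCR against ALL (0.94) was 0.95 with the CPM filter, 0.92 with limma voom and 0.94 with Sertoli scaling. The r with Low-VCR against ALL (0.88) was 0.84 and 0.87 with the latter settings, and that of Low-VCR with High-VCR (0.93) was 0.91 with limma voom. Camera's direction turned for lists on leaving out 1 library. In High-VCR against VCR this held for mitotic genes (median 0.29) without High-VCR 2 (-0.05) and VCR 1 (0.06), range -0.05 to 0.56, and without VCR 1 for pachytene genes (0.07, range -0.19 to 0.90) and round spermatids (0.09, range 0.09 to 0.84). In the High-VCR interaction it held without VCR 1 for pachytene genes (0.06, range -0.10 to 0.95) and round spermatids (0.10, range 0.10 to 0.88).

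A replicate block was tried as the labels number the samples 1 to 4 per group. These numbers did not pair them: of 40 same-numbered pairs, with r from -0.38 to 0.53, 5 were over 0.1. A sample correlated best with its own number in 18 of 80 comparisons with another group (1 in 4 by chance). With the block 294 genes were called for High-VCR against Low-VCR, 9 for the Low-VCR interaction, 12771 for VCR against NC and 4144 for Low-VCR against VCR. With it 1 list call was lost, that of NRF2 genes in Low-VCR against VCR (-0.47, adjusted p 0.058).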

Other observations

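Relative to the Sertoli score of the same library, the germ cell scores tested were lower after vincristine, with the largest difference in round spermatids; differences between stages were not tested. In VCR relative to NC the difference was -1.22 for undifferentiated spermatogonia, -2.07 for differentiating spermatogonia, -3.44 for leptotene and zygotene cells, -3.94 for pachytene to diplotene spermatocytes, -5.51 for round spermatids and -4.84 for elongating spermatids (log2, n = 4 per group). The SD of the last 4 in VCR was 1.39, 1.88, 2.07 and 2.34, and without VCR 1 they were -2.86, -3.12, -4.51 and -3.73, each at an exact permutation p of 0.0286. In Low-VCR relative to ALL it was -1.17, -1.44, -2.10, -2.53, -2.98 and -2.46, and in High-VCR relative to ALL -1.24, -2.14, -3.06, -3.21, -4.62 and -3.26. Each had an exact permutation p of 0.0286, the smallest possible (adjusted p 0.0332 over 36 tests). This set of tests was chosen after the data had been seen.

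Among somatic cells, peritubular scores were lower relative to Sertoli scores in all comparisons (-0.73, -0.70 and -0.68, exact permutation p 0.0286). Leydig scores differed by 0.51 (p 0.0286) in VCR, -0.01 (p 0.971) in Low-VCR and 0.24 (p 0.0571) in High-VCR, and endothelial scores by 0.68 (p 0.0286), -0.10 (p 0.629) and 0.09 (p 0.686), by exact permutation. For macrophage scores the differences were 0.82 (exact permutation p 0.0286), 0.13 (p 0.429) and 0.51 (p 0.0286). Whether these changes differ between the treated groups was not tested. Interferon scores (1.02, 0.69 and 0.57) and inflammatory scores (1.32, 0.40 and 0.81) were higher in VCR, Low-VCR and High-VCR, each at an exact permutation p of 0.0286.

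Of the 20 genes listed at 0 in some of the 8 untreated libraries despite a mean of at least 100 counts, the ribosomal protein gene Rps14 was listed at 0 in NC 3 and NC 4 with up to 1051 counts in others, Srsf11 and Oaz1 at 0 in NC 2 with up to 1384 and 805, and Pi4ka at 0 in 6 of the 8 with up to 1280.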
